A study of Mus musculus with 18 samples.

How the data were processed

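Mouse small intestinal organoid cultures (C57BL/6J) were sequenced for RNA, 18 libraries in 6 groups of 3. Per the labels' protocols, crypts were grown in Matrigel, a basement membrane extract, with ENR medium (EGF, Noggin and R-spondin 1), or in collagen type I with ENRW medium. Collagen cultures for the comparison with villi received 25% cWRNE medium in place of ENRW. Villi came from the 3 cm of intestine next to the stomach outlet and were grown in collagen type I with 25% cWRNE medium. 5-Fluorouracil (5-FU), a pyrimidine analog, was added at 40 µM from day 4, and all cultures were harvested on day 6. The series states that the 3 replicates of a group are biological. Libraries were made with the SMART-Seq mRNA and Nextera XT kits and sequenced on a NovaSeq X Plus.

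Estimated counts per gene and TPM were deposited for each library, per the file headers. Per the submitters' processing notes, bcl2fastq 2.20 and DRAGEN were used with the GRCm39 (mm39) build; the gene annotation, the counting tool and any filter were not stated. In the deposited table of 55414 genes, 67.8% of the nonzero estimated counts were whole numbers to within 1e-9, and the authors had applied no scaling between libraries to them. The deposited TPM summed to 1000000 in each library. Library totals ranged from 22.3 M to 34.5 M estimated counts. Gene symbols were found for 52081 gene identifiers and not for 3333; in each library at least 99.73% of counts fell on genes with a symbol, and 67 symbols were carried by more than 1 identifier. The genome annotation at hand was of another build than the deposited table, so no coordinates are given.

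Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F-tests with TMM scaling. The filterByExpr filter was used with a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The 5-FU and matrix comparisons shared a fit of 12 libraries, and the villus comparisons shared a fit of 9 libraries, with group as the only term. A further comparison, cWRNE against ENRW in collagen, was chosen after the data were seen and fitted over all 18 libraries. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Levels are given as counts per M (CPM) with TMM scaling over the 18 libraries, as mean and standard deviation (SD, n = 3). A count of 0 over a group allows up to 3 counts; folds against such a group are given as at least that size, and intervals and floors cover counting error only.

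The 7 comparisons among the 6 groups, 27 gene lists (419 genes), the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered p53 targets, fetal-like and regenerative epithelium, YAP targets, Wnt targets, crypt stem cells, Paneth, goblet, enteroendocrine, tuft and absorptive enterocyte cells, and the villus tip. They also covered G2/M phase, S phase, 5-FU metabolism, interferon response, NF-kB and inflammation, integrins with laminins and focal adhesions, the unfolded protein and integrated stress responses, cholesterol synthesis, and immediate early with heat shock genes. The others held markers of the proximal and distal small intestine, of stomach and Brunner glands, and of mesenchymal, immune, endothelial, and enteric glia and neuron cells. Of the list genes, 1 (Muc6) had no matching identifier. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were run beside it.

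Genes named in the text were chosen by 3 rules. The first took, per comparison and direction, the 8 genes with the largest log2 fold change among those called, with groups that did not overlap and a mean of at least 10 CPM in the higher group, bare gene models excluded. Chance gives no overlap between 3 and 3 values for 10% of genes. For the interaction, the first rule used the adjusted p alone in place of the overlap. The second took from each described list up to 4 members with the smallest adjusted p. The third named a set of marker genes whatever their result. Some genes that these rules name are not reported here.

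The alternatives were an absolute log2 fold change of at least 1, DESeq2 1.42.0, RLE size factors, library totals without scaling, no filter beyond 1 count, at least 10 CPM in at least 3 libraries, all 18 libraries in one fit, only the compared groups, a replicate block, and leaving out each replicate in turn. Limma-trend on the deposited TPM (log2 of TPM plus 1, at least 1 TPM in at least 3 libraries) and VIL replicate 1 as the only villus-derived library were added after the data were seen. Replicates with the same number correlated across 9720 genes, after group means were removed, at 0.202 to 0.565 for the 6 pairs of both 5-FU comparisons, and 16 of 18 such pairs in the fit of 12 libraries exceeded 0.1. The replicate block was therefore reported beside these counts. In the villus fit 6 of 9 pairs exceeded 0.1, and the libraries were not treated as paired. No 2 of the 18 pairs of replicates within a group were duplicates of one another, since the lowest chi-square per degree of freedom was 11.3.

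The fits were tested on simulated counts with 200 changed genes among genes with the means and totals of the real libraries. At a true fold change of 2, the share recovered was 50.7% for 5-FU in Matrigel, 52.3% for 5-FU in collagen, 26.2% for the interaction, 59.1% for collagen against Matrigel, and 22.2% for villus-derived against crypt-derived in collagen. It was 25% for villus-derived against crypt-derived in Matrigel, 16.7% for crypt-derived in collagen with cWRNE against Matrigel and 37.5% for cWRNE against ENRW. At a fold change of 4 the shares were 57.8% to 74.2%, and 1 to 6 unchanged genes were called per comparison. Among 25 unchanged lists, 1 was called for the interaction and 0 for each other comparison.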

Results

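RNA was sequenced from 18 cultures of mouse small intestinal organoids, 3 in each of 6 groups. MG_Control and MG_5FU held crypt-derived organoids in Matrigel with ENR medium, without and with 5-fluorouracil (5-FU). COL_Control and COL_5FU held crypt-derived organoids in collagen type I with ENRW medium, without and with 5-FU. COL_cWRNE held crypt-derived organoids, and VIL villus-derived organoids, in collagen type I with 25% cWRNE medium. Total estimated counts per library (M) were 26.2, 27.2 and 31.5 in MG_Control, 30.0, 27.0 and 22.3 in MG_5FU, and 28.8, 26.4 and 25.8 in COL_Control. They were 27.5, 29.3 and 33.4 in COL_5FU, 30.3, 33.2 and 29.8 in COL_cWRNE, and 27.6, 34.5 and 23.1 in VIL. By Xist and 4 Y-linked genes, replicate 2 of each group came from male tissue and the others from female tissue, so sex was balanced across the groups. COL_Control replicate 3 was the exception, with 738 Y-linked counts beside a female level of Xist.

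The 5-FU comparison in Matrigel asked how crypt-derived organoids responded there. Most p53 target genes rose, most cell cycle and cholesterol synthesis genes fell, and most markers of Paneth, enteroendocrine and absorptive cells and of fetal-like epithelium rose. With an estimated correlation, the list call of the p53 targets held and those of the other lists ended. Cdkn1a (ENSMUSG00000023067.15), which encodes a cyclin-dependent kinase inhibitor, went from 102 ± 35.5 to 989 ± 111 CPM (SD, n = 3). Mki67, a proliferation marker, went from 156 ± 8.82 to 56.7 ± 1.22 CPM, and Lyz1, the Paneth cell lysozyme, from 3380 ± 462 to 11800 ± 1780 CPM. Olfm4, a marker of crypt base cells, went from 3820 ± 524 to 562 ± 136 CPM. In all, 5128 of 16611 genes tested passed by edgeR, 3188 higher and 1940 lower, and 5434 passed with a replicate block. The share of passing genes that were higher was 62.2%, and 44.6% with library totals in place of TMM scaling.

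The p53 target genes gave the largest set of calls among the lists in Matrigel. Of 32 measured, 26 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.18e-18, and adjusted p = 0.029 with an estimated correlation). This was the only list call, among 109 in the 7 planned comparisons, that held with an estimated correlation. Mdm2 (ENSMUSG00000020184.16), which encodes the ubiquitin ligase of p53, rose by 2.96 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 1.09e-08) and Cdkn1a by 3.34 ± 0.2 (edgeR adjusted p = 9.95e-08). Phlda3 rose by 4.55 ± 0.2, Zmat3 by 3.76 ± 0.17, and Aen, an apoptosis-enhancing nuclease, by 1.99 ± 0.1. Most cell cycle genes fell. Of 22 S phase and DNA replication genes, 0 rose and 21 fell, also adjusted over the list alone (camera adjusted p = 5.25e-16, and adjusted p = 0.141 with an estimated correlation). Tk1, which encodes thymidine kinase, changed by -2.15 ± 0.14, Rrm1, a subunit of ribonucleotide reductase, by -1.36 ± 0.13, and the helicase genes Mcm6 and Mcm5 by -1.31 ± 0.12 and -1.08 ± 0.11. Of 21 G2/M phase genes, 0 rose and 18 fell, 19 of them adjusted over the list alone (camera adjusted p = 3.92e-13, and adjusted p = 0.175 with an estimated correlation). Mki67 changed by -1.40 ± 0.16 (edgeR adjusted p = 1.99e-05) and the cyclin gene Ccnb2 by -1.58 ± 0.13. Of the 15 genes of 5-FU metabolism, 5 rose and 7 fell (camera adjusted p = 0.156). Tyms, which encodes thymidylate synthase, the target of the drug's active metabolite, changed by -0.58 ± 0.11 (edgeR adjusted p = 0.00123).

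Among lineage markers, all 16 measured Paneth cell genes rose, also adjusted over the list alone (camera adjusted p = 5.48e-12, and adjusted p = 0.141 with an estimated correlation). The defensin genes Defa23 and Defa30 rose by 1.69 ± 0.11 and 1.74 ± 0.12, Ang4 by 2.14 ± 0.16 and Lyz1 by 1.85 ± 0.15. Members of the defensin family, and Lyz1 and Lyz2, are paralogs with similar sequence, so their single values are uncertain. Of 19 enteroendocrine cell genes, 16 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.209 with an estimated correlation), among them Neurog3 (2.49 ± 0.27) and Tph1 (2.09 ± 0.24). Of 24 absorptive enterocyte genes, 17 rose and 0 fell, 21 and 0 adjusted over the list alone (camera adjusted p = 3.65e-06, and adjusted p = 0.241 with an estimated correlation), among them Krt20 (2.32 ± 0.16), Apoa1 (2.26 ± 0.23) and Vil1 (0.75 ± 0.09). Of 13 tuft cell genes, 6 rose and 0 fell (camera adjusted p = 0.0233, and adjusted p = 0.211 with an estimated correlation). Of 13 goblet cell genes, 6 rose and 1 fell (camera adjusted p = 0.0957), with Clca1 at 2.28 ± 0.21 and the mucin gene Muc2 at 1.51 ± 0.14. Of 7 villus tip genes, 3 rose and 1 fell (camera adjusted p = 0.0816). All 4 distal small intestine genes rose (camera adjusted p = 0.00644, and adjusted p = 0.141 with an estimated correlation), among them Slc10a2, the ileal bile acid transporter, at 2.81 ± 0.35. Of 6 proximal small intestine genes 1 rose (camera adjusted p = 0.322), and of 5 gastric and Brunner gland genes 4 rose and 1 fell (camera adjusted p = 0.319). Of 20 crypt stem cell genes, 3 rose and 8 fell, 3 and 10 adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.386 with an estimated correlation). Olfm4 fell by 2.71 ± 0.3, whereas Tnfrsf19 rose by 1.96 ± 0.21 and Sox9 by 0.83 ± 0.11.

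Of 24 genes of fetal-like and regenerative epithelium measured in Matrigel, 21 rose and 0 fell, 23 and 0 adjusted over the list alone (camera adjusted p = 6.1e-13, and adjusted p = 0.157 with an estimated correlation). Anxa8 rose by 4.83 ± 0.35, Cldn4 by 2.68 ± 0.18, Il1rn by 3.60 ± 0.28, Ly6a, which encodes Sca-1, by 3.59 ± 0.37 and Clu, which encodes clusterin, by 2.37 ± 0.26. Anxa1 rose by 2.87 ± 0.38. Of 20 YAP target genes, 12 rose and 0 fell (camera adjusted p = 3.65e-06, and adjusted p = 0.157 with an estimated correlation), among them Ccn2 (4.26 ± 0.34) and F3 (2.63 ± 0.24). Of 18 Wnt target genes, 9 rose and 2 fell, 10 and 3 adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.387 with an estimated correlation), among them Ccnd1 (2.05 ± 0.19) and Cd44 (1.35 ± 0.13). Of 11 immediate early and heat shock genes, 8 rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p = 1.52e-05, and adjusted p = 0.194 with an estimated correlation), with Egr1 at 3.08 ± 0.18. Of 16 cholesterol synthesis genes, 1 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 3.04e-12, and adjusted p = 0.141 with an estimated correlation). Fdps changed by -1.63 ± 0.12 and Sqle, which encodes squalene epoxidase, by -1.57 ± 0.12. Of 15 genes of the unfolded protein and integrated stress responses, 0 rose and 11 fell (camera adjusted p = 1.46e-07, and adjusted p = 0.141 with an estimated correlation). Trib3 changed by -2.65 ± 0.2, and Asns, which encodes asparagine synthetase, by -1.15 ± 0.1.

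Other lists gave no call in this comparison. Of 15 interferon response genes 4 rose and 1 fell (camera adjusted p = 0.106), of 14 NF-kB and inflammatory genes 6 rose and 1 fell (camera adjusted p = 0.215), and of 21 integrin, laminin and focal adhesion genes 7 rose and 1 fell (camera adjusted p = 0.0869). The 2 mesenchymal genes measured, Vim and Acta2, did not pass and were too few for a list test. Of 3 immune cell genes 1, Lyz2, rose; the list's median was -0.61 and its mean -0.04, while camera gave the upward direction (adjusted p = 0.569). Of 4 endothelial genes 0 passed (camera adjusted p = 0.928), and of 3 enteric glia and neuron genes 2 rose (camera adjusted p = 0.344). Among single genes with the largest increases, Pakap and Ggta1 were each at least 309-fold higher, with 0 counts in MG_Control and 10.5 ± 2.67 and 10.5 ± 2.68 CPM with 5-FU. Mcam went from 1.15 ± 0.21 to 172 ± 38.1 CPM, Crip2 from 2.99 ± 1.67 to 402 ± 40.1 CPM and Zfp365 from 0.0507 ± 0.0877 to 53.1 ± 14.8 CPM. Ano3, with 2 counts over MG_Control, reached 29.1 ± 8.29 CPM, Casp14 reached 15.4 ± 2.93 CPM and Rgs5 15.4 ± 2.64 CPM. Among the largest decreases were those of Prelp (-4.34 ± 0.53), Nox1 (-3.49 ± 0.52), the water channel gene Aqp4 (-3.40 ± 0.4), Slc16a12 (-3.28 ± 0.67), the fatty acid desaturase gene Fads1 (-3.27 ± 0.19), Sfrp5 (-3.24 ± 0.48) and Ak4 (-3.17 ± 0.62). Lgr5 (ENSMUSG00000020140.16), the receptor that marks crypt stem cells, changed by -0.72 ± 0.25 (edgeR adjusted p = 0.041). Its call ended without MG_Control replicate 1 or 3, or without any 1 of the MG_5FU replicates, with log2 fold changes of -0.77 to -0.52 (edgeR adjusted p of 0.0742 to 0.173). The counts of Zfp365 in MG_Control came from replicate 3 alone, those of Ano3 and Rgs5 from replicate 1 and those of Casp14 from replicate 2, and without that library the group was at 0 counts. Without MG_Control replicate 3 the log2 fold change of Casp14 went from 7.56 to 6.95 and that of Rgs5 from 6.81 to 6.19, and without MG_5FU replicate 1 that of Ak4 went to -4.24.

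The 5-FU comparison in collagen asked the same question with ENRW medium. Here too most p53 target and fetal-like genes rose and most cell cycle genes fell, whereas 10 of 13 goblet, 11 of 24 absorptive enterocyte and 5 of 16 Paneth cell genes fell. All of these list calls ended with an estimated correlation. Cdkn1a went from 181 ± 29.7 to 919 ± 21.1 CPM (SD, n = 3), Mki67 from 157 ± 16.5 to 58.2 ± 15.8 CPM and Olfm4 from 153 ± 52.1 to 8.08 ± 3.5 CPM. Lyz1 was at 1530 ± 207 CPM without and 1680 ± 182 CPM with 5-FU. In all, 5862 of 16611 genes passed by edgeR, 3094 higher and 2768 lower, and 6189 passed with a replicate block. The share that were higher was 52.8%, and 41.7% with library totals in place of TMM scaling. Without COL_Control replicate 3, 4817 genes passed.

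Of 32 p53 target genes, 25 rose and 3 fell in collagen, 26 and 3 adjusted over the list alone (camera adjusted p = 4.94e-15, and adjusted p = 0.0523 with an estimated correlation). Mdm2 rose by 3.05 ± 0.13 (edgeR adjusted p = 1.31e-08), Fas by 3.88 ± 0.19, Perp by 2.09 ± 0.1, Sesn2 by 2.21 ± 0.12 and Cdkn1a by 2.31 ± 0.2 (edgeR adjusted p = 2.06e-06). Of 24 fetal-like genes, 18 rose and 0 fell, 21 and 1 adjusted over the list alone (camera adjusted p = 2.64e-07, and adjusted p = 0.439 with an estimated correlation). Anxa8 rose by 5.75 ± 0.28, Ereg by 3.09 ± 0.34, Il33 by 2.83 ± 0.32, Anxa1 by 2.17 ± 0.36, Clu by 1.73 ± 0.25 and Ly6a by 1.31 ± 0.33. Of 20 YAP target genes, 11 rose and 3 fell (camera adjusted p = 0.00535, and adjusted p = 0.48 with an estimated correlation), with Ccn2 at 2.76 ± 0.3. Of 21 integrin, laminin and focal adhesion genes, 10 rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 9.42e-05, and adjusted p = 0.439 with an estimated correlation), among them Itgb4 (1.75 ± 0.12). Of 21 G2/M phase genes, 1 rose and 16 fell, 1 and 18 adjusted over the list alone (camera adjusted p = 3.22e-07, and adjusted p = 0.48 with an estimated correlation). Mki67 changed by -1.46 ± 0.16 and Bub1b by -1.50 ± 0.12. Of 22 S phase genes, 0 rose and 12 fell, also adjusted over the list alone (camera adjusted p = 0.000203, and adjusted p = 0.525 with an estimated correlation), with Tk1 at -1.03 ± 0.14. Tyms was at 0.17 ± 0.11 (edgeR adjusted p = 0.24). Of 16 cholesterol synthesis genes, 1 rose and 15 fell (camera adjusted p = 1.06e-07, and adjusted p = 0.439 with an estimated correlation), among them Insig1 at -3.40 ± 0.25. Of 15 genes of the unfolded protein and integrated stress responses, 1 rose and 13 fell, 1 and 14 adjusted over the list alone (camera adjusted p = 8.1e-08, and adjusted p = 0.156 with an estimated correlation), with Trib3 at -2.78 ± 0.2 and Chac1 at -2.86 ± 0.22.

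Of 24 absorptive enterocyte genes, 3 rose and 11 fell, 4 and 12 adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.556 with an estimated correlation). The brush border genes Mgam and Slc5a1 changed by -2.30 ± 0.21 and -1.69 ± 0.2. Of 13 goblet cell genes, 1 rose and 10 fell (camera adjusted p = 0.00179, and adjusted p = 0.439 with an estimated correlation), with Fcgbp at -1.51 ± 0.2. Of 16 Paneth cell genes, 0 rose and 5 fell, 0 and 4 adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.556 with an estimated correlation). Lyz1 was at 0.10 ± 0.15 (edgeR adjusted p = 0.632). Of 19 enteroendocrine genes, 5 rose and 0 fell (camera adjusted p = 0.104), with Gcg at 1.77 ± 0.25. Of 18 Wnt target genes, 8 rose and 2 fell (camera adjusted p = 0.0139, and adjusted p = 0.48 with an estimated correlation). Of 13 tuft cell genes 2 rose and 2 fell (camera adjusted p = 0.68); the list's median was -0.61 and its mean 0.04, since Alox5, which encodes 5-lipoxygenase, rose by 5.19 ± 0.52. Olfm4 fell by 4.26 ± 0.33 and Lgr5 by 0.98 ± 0.25 (edgeR adjusted p = 0.00728), whereas Sox9 rose by 1.19 ± 0.11. Of 20 crypt stem cell genes in all, 5 rose and 8 fell (camera adjusted p = 0.113). Among the largest increases after Anxa8 were those of Robo3 (5.42 ± 0.57), Zfp365 (5.29 ± 0.41), Alox5, Ano3 (5.16 ± 0.33), Mcam (4.83 ± 0.19) and Gna15 (4.81 ± 0.55). The largest decreases were those of Prelp (-5.09 ± 0.59), Dmbt1 (-4.97 ± 0.64), the urea cycle genes Otc (-4.81 ± 0.42) and Cps1 (-4.08 ± 0.5), Aldh1l2 (-4.45 ± 0.36), the diamine oxidase gene Aoc1 (-4.28 ± 0.62), Olfm4 and Hkdc1 (-4.11 ± 0.36). In a fit of all 18 libraries, the call of Lgr5 ended. Without COL_5FU replicate 3, Prelp was at -6.96, Dmbt1 at -5.59, Otc at -5.40, Cps1 at -4.94 and Aoc1 at -7.09. Without COL_Control replicate 1, Zfp365 was at 6.07 and Gna15 at 5.64, without COL_Control replicate 2 Dmbt1 was at -4.24, and without COL_Control replicate 3 Alox5 was at 5.87.

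**Figure D1:**
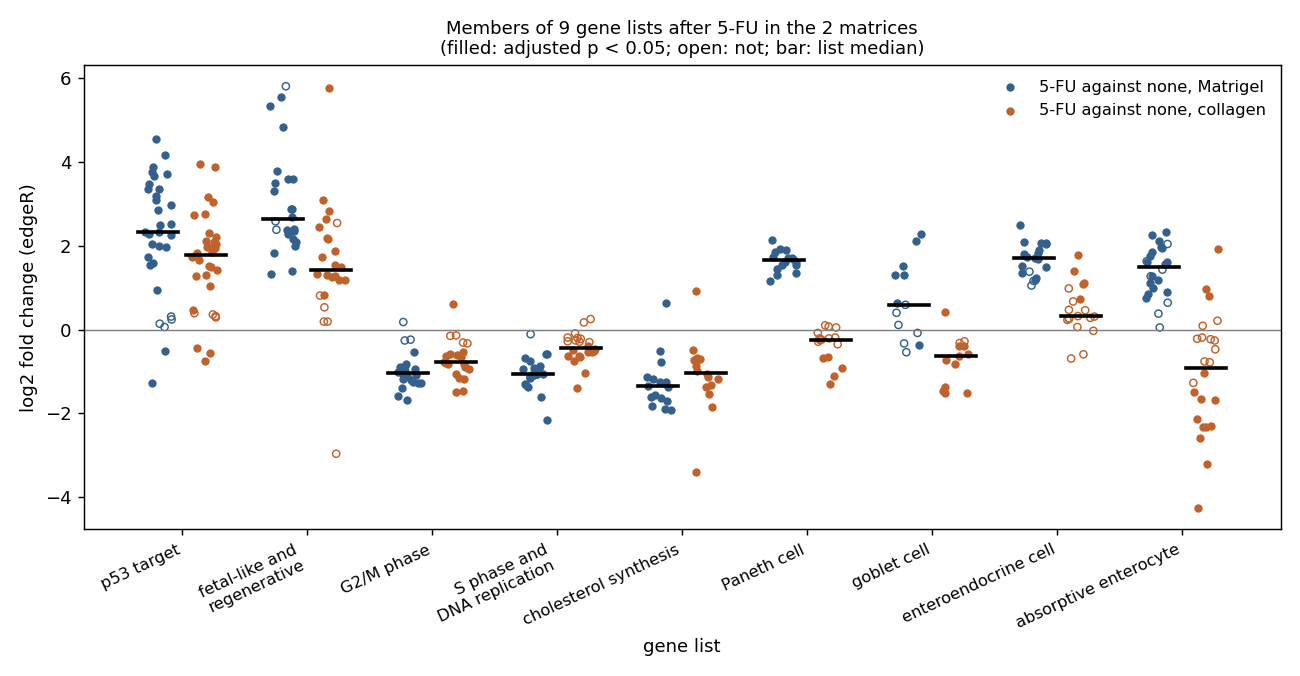
Log2 fold changes (edgeR, vertical axis) of the members of 9 gene lists with 5-FU against none, in Matrigel (blue) and collagen (orange). Filled points had an adjusted p under 0.05, open points did not, and bars are list medians. The Paneth cell median was 1.65 in Matrigel and -0.24 in collagen, and the p53 target medians were 2.33 and 1.77.

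The interaction tested whether the 5-FU response differed between the 2 culture systems, matrix and medium together, and its sign is the response in collagen minus that in Matrigel. A lower response can thus be a smaller rise or a larger fall in collagen, and a higher one a larger rise or a smaller fall. The response was lower in collagen for 1047 genes and higher for 313, 1360 of 16611 genes tested by edgeR, and 1596 with a replicate block. The lower ones included markers of Paneth, goblet, enteroendocrine and absorptive cells, whose list calls ended with an estimated correlation. All 16 Paneth cell genes had a lower response in collagen, also adjusted over the list alone, with a median of -1.87 (camera adjusted p = 1.1e-20, and adjusted p = 0.0698 with an estimated correlation). Of 24 absorptive enterocyte genes, 17 were lower and 0 higher, 20 and 0 adjusted over the list alone (camera adjusted p = 3.54e-13, and adjusted p = 0.149 with an estimated correlation), among them Krt20 (-2.51 ± 0.22). Of 13 goblet cell genes, 8 were lower and 0 higher, 11 and 0 adjusted over the list alone (camera adjusted p = 3.99e-07, and adjusted p = 0.0698 with an estimated correlation), among them Clca1 (-3.11 ± 0.29). Of 19 enteroendocrine cell genes, 6 were lower and 0 higher, 9 and 0 adjusted over the list alone (camera adjusted p = 5.41e-06, and adjusted p = 0.297 with an estimated correlation), among them Tac1 (-2.09 ± 0.3). All 4 distal small intestine genes were lower (camera adjusted p = 0.000164, and adjusted p = 0.0698 with an estimated correlation), with Slc51a at -3.02 ± 0.47 and Slc10a2 at -2.88 ± 0.46. Of 15 interferon response genes, 4 were lower and 0 higher, 8 and 0 adjusted over the list alone (camera adjusted p = 0.000504, and adjusted p = 0.149 with an estimated correlation), with Irf7 at -1.78 ± 0.3.

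The p53 target genes were 12 lower and 0 higher of 32 by the interaction, 20 and 0 adjusted over the list alone (camera adjusted p = 2.36e-05, and adjusted p = 0.165 with an estimated correlation). Zmat3 was at -1.72 ± 0.21, Phlda3 at -1.84 ± 0.24 and Cdkn1a at -1.03 ± 0.26, while Mdm2 was at 0.09 ± 0.17 (edgeR adjusted p = 0.831). Of 24 fetal-like genes, 9 were lower and 0 higher, 12 and 0 adjusted over the list alone (camera adjusted p = 0.000127, and adjusted p = 0.403 with an estimated correlation), with Cldn4 at -1.85 ± 0.24 and Il1rn at -2.07 ± 0.36. Among S phase genes the sign was the opposite, with 10 of 22 higher and 0 lower, 16 and 0 adjusted over the list alone (camera adjusted p = 4.84e-12, and adjusted p = 0.215 with an estimated correlation). Tk1 was at 1.12 ± 0.19 and Tyms at 0.75 ± 0.16 (edgeR adjusted p = 0.00893). Mki67 was at -0.06 ± 0.22 (edgeR adjusted p = 0.922) and Lgr5 at -0.26 ± 0.34 (edgeR adjusted p = 0.742). For p53 target and fetal-like genes, a lower response was not always a lower level with 5-FU, since most were already higher in collagen without it. Il1rn went from 13.9 to 162 CPM in Matrigel and from 157 to 464 CPM in collagen. Phlda3 went from 11.4 to 257 CPM and from 58.7 to 394 CPM. With 5-FU, Cdkn1a was at 989 CPM in Matrigel and 919 CPM in collagen, and Zmat3 at 104 and 92.3 CPM. In a fit of all 18 libraries 521 genes passed, and the calls of Tyms and Cdkn1a ended. The call of Cdkn1a also ended without MG_Control replicate 2, MG_5FU replicate 1 or 3, COL_Control replicate 1 or 3, or any 1 of the COL_5FU replicates, with values of -1.04 to -0.91 (edgeR adjusted p of 0.0536 to 0.0715). The share that were higher was 23%, 33.0% with library totals, 33.7% with RLE size factors and 57.8% with limma-trend on TPM.

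Collagen against Matrigel without 5-FU compared the 2 culture systems before treatment, with matrix and medium changing together. In collagen with ENRW medium, most fetal-like, YAP target and immediate early genes were higher. Most markers of absorptive, Paneth, goblet and enteroendocrine cells, and 6 of 13 of tuft cells, were lower, and these list calls ended with an estimated correlation. Ly6a was at 17.0 ± 6.49 CPM in Matrigel and 544 ± 224 CPM in collagen (SD, n = 3), Clu at 125 ± 9.43 and 1070 ± 423 CPM, Lyz1 at 3380 ± 462 and 1530 ± 207 CPM, and Olfm4 at 3820 ± 524 and 153 ± 52.1 CPM. Lgr5 was higher in collagen by 1.53 ± 0.25 (edgeR adjusted p = 0.000412), and Mki67 was at 0.00 ± 0.16 (edgeR adjusted p = 0.985). In all, 5188 of 16611 genes passed by edgeR, 2628 higher and 2560 lower, and 5541 with a replicate block. The share that were higher was 50.7%, and 72.8% with limma-trend on TPM. Without COL_Control replicate 3, 4485 genes passed.

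Of 24 fetal-like genes, 21 were higher and 0 lower in collagen, 22 and 0 adjusted over the list alone (camera adjusted p = 8.9e-14, and adjusted p = 0.118 with an estimated correlation). Ly6a was higher by 5.00 ± 0.39, Anxa1 by 4.31 ± 0.4, Clu by 3.09 ± 0.26 and Emp1 by 1.87 ± 0.11. Of 20 YAP target genes, 15 were higher and 1 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 3.47e-08, and adjusted p = 0.118 with an estimated correlation), with Ccn2 at 4.91 ± 0.35 and Myof at 3.31 ± 0.32. Of 11 immediate early and heat shock genes, 10 were higher and 0 lower (camera adjusted p = 1.31e-10, and adjusted p = 0.118 with an estimated correlation), with Egr1 at 4.23 ± 0.19 and Fos at 3.75 ± 0.25. Of 21 integrin, laminin and focal adhesion genes, 13 were higher and 0 lower, 16 and 0 adjusted over the list alone (camera adjusted p = 3.19e-06, and adjusted p = 0.187 with an estimated correlation), among them Flna (1.93 ± 0.22). Of 14 NF-kB and inflammatory genes, 11 were higher and 0 lower (camera adjusted p = 2.97e-05, and adjusted p = 0.246 with an estimated correlation), among them Icam1 (2.38 ± 0.28). Of 32 p53 target genes, 21 were higher and 2 lower, 23 and 3 adjusted over the list alone (camera adjusted p = 4.91e-08, and adjusted p = 0.118 with an estimated correlation), with Epha2 at 2.29 ± 0.15, Plk2 at 2.75 ± 0.19, Mdm2 at 1.03 ± 0.12 and Cdkn1a at 0.83 ± 0.19. Tyms was at -0.12 ± 0.11 (edgeR adjusted p = 0.429). Among the largest single increases were those of Wnt7b, at least 347-fold higher with 0 counts in MG_Control, Cyp1b1 (9.32 ± 0.78), Gcnt1 (7.09 ± 0.64), the basement membrane collagen gene Col4a1 (7.04 ± 0.77), Efemp1 (6.66 ± 0.68) and Msn (6.27 ± 0.91). Ankrd1, a YAP target with 2 counts over MG_Control, stood at 14.7 ± 11.4 CPM in collagen. In MG_Control, replicate 2 alone held counts of Cyp1b1 and Gcnt1 and replicate 3 alone those of Efemp1 and Msn. Without that library the group was at 0 counts and the values, 12.84, 11.37, 11.37 and 11.74, depended on the prior count. Col4a1 was at 8.31 without MG_Control replicate 1, and without MG_Control replicate 3 it was at 6.41, Cyp1b1 at 8.71 and Gcnt1 at 6.47. Without COL_Control replicate 1, Msn was at 5.60 and the log2 fold change of Ankrd1 went from 9.08 to 8.30.

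Absorptive enterocyte genes, 24 measured, were 0 higher and 20 lower in collagen than in Matrigel, also adjusted over the list alone (camera adjusted p = 1.91e-13, and adjusted p = 0.118 with an estimated correlation). The apolipoprotein genes Apoa4 and Apoa1 were at -4.66 ± 0.29 and -4.01 ± 0.26, and the glucose transporter gene Slc2a2 at -4.97 ± 0.34. Of 16 Paneth cell genes, 0 were higher and 15 lower (camera adjusted p = 4.24e-12, and adjusted p = 0.118 with an estimated correlation), with Defa5 at -2.87 ± 0.13 and Lyz1 at -1.15 ± 0.15. Of 13 goblet cell genes, 0 were higher and 10 lower, 0 and 11 adjusted over the list alone (camera adjusted p = 1.59e-06, and adjusted p = 0.118 with an estimated correlation), with Zg16 at -3.95 ± 0.35. Of 19 enteroendocrine genes, 0 were higher and 13 lower, 0 and 15 adjusted over the list alone (camera adjusted p = 5.96e-07, and adjusted p = 0.246 with an estimated correlation), with Chga at -2.12 ± 0.26. Of 13 tuft cell genes, 0 were higher and 6 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.118 with an estimated correlation), with Rgs13 at -2.83 ± 0.43. Of 21 G2/M phase genes, 2 were higher and 0 lower (camera adjusted p = 0.742). Olfm4 was at -4.65 ± 0.33. The other large decreases were those of Cfhr2 (-8.14 ± 0.7), the transporter gene Slc5a4b (-8.07 ± 0.41), Reg3a (-7.38 ± 0.3), the cytochrome gene Cyp3a11 (-7.12 ± 0.64), Reg1 (-6.96 ± 0.37), Ugt2b5 (-6.72 ± 0.47), Acer1 (-6.70 ± 0.78) and Spink1 (-6.60 ± 0.37). Without COL_Control replicate 3, Zg16 was at -4.54, Rgs13 at -3.50, Cyp3a11 at -7.79, Reg1 at -7.68 and Spink1 at -7.42. The counts of Cfhr2 in COL_Control came from replicate 2 alone, and without it the value, -12.18, depended on the prior count. Without replicate 1 Cfhr2 was at -7.55 and Acer1 at -6.11, and Acer1 was at -7.64 without replicate 2.

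More lists were called between collagen and Matrigel. Of 18 Wnt target genes, 7 were higher and 1 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0213, and adjusted p = 0.427 with an estimated correlation). Of 15 interferon response genes, 6 were higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00801, and adjusted p = 0.185 with an estimated correlation). Of 15 unfolded protein and integrated stress response genes, 0 were higher and 6 lower (camera adjusted p = 0.0213, and adjusted p = 0.392 with an estimated correlation).

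**Figure D2:**
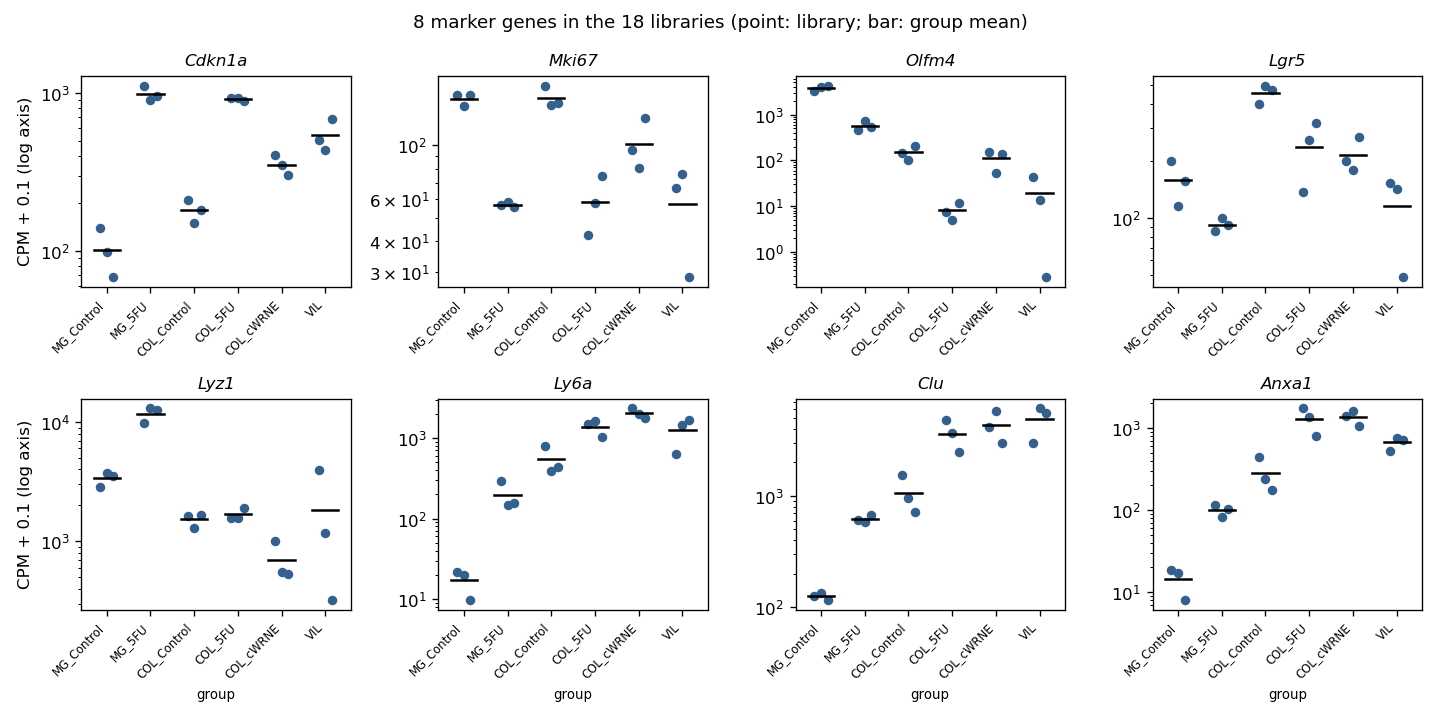
CPM plus 0.1 (vertical log axis) of 8 marker genes in the 18 libraries by group (horizontal axis); each point is a library and each bar a group mean. Lyz1 had a mean of 11800 CPM in MG_5FU and 1680 CPM in COL_5FU, and the mean of Olfm4 fell from 3820 CPM in MG_Control to 8.08 CPM in COL_5FU.

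The comparison of villus-derived with crypt-derived cultures, both in collagen with cWRNE medium, asked how the 2 tissue sources differed. Gut region was stated for villi alone, so it may differ too. Villus-derived cultures held transcripts of immune and mesenchymal cells at far higher levels than the crypt-derived ones, and 7 of 24 absorptive enterocyte genes were higher. These list calls ended with an estimated correlation. Lyz2, the macrophage lysozyme, was at 2180 ± 1290 CPM in VIL and 1.83 ± 1.01 CPM in COL_cWRNE (SD, n = 3), and the collagen gene Col3a1 was at least 4030-fold higher, at 134 ± 115 CPM against 0 counts, and at least 2500-fold without VIL replicate 2. All 9 immune and all 9 mesenchymal genes measured were higher (camera adjusted p = 1e-14 and 1.35e-10, and adjusted p = 0.25 with an estimated correlation for both), with median log2 fold changes of 9.52 and 8.05 when genes at 0 are set to their bound. The sum over the 9 immune genes was 1002.8, 2858 and 4208.9 CPM in VIL replicates 1, 2 and 3, and that over the 9 mesenchymal genes 50.5, 734.7 and 702.3 CPM. Fabp2, which encodes the intestinal fatty acid binding protein, was higher by 2.19 ± 0.18 (edgeR adjusted p = 0.000411) and Krt20 by 3.07 ± 0.49, or by 2.21 without VIL replicate 3. In all, 1276 of 16699 genes passed by edgeR, 949 higher and 327 lower.

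Among 24 absorptive enterocyte genes, 7 were higher and 0 lower in villus-derived cultures, 15 and 1 adjusted over the list alone (camera adjusted p = 1.72e-05, and adjusted p = 0.361 with an estimated correlation). Of 7 villus tip genes, 3 were higher and 0 lower (camera adjusted p = 0.00526, and adjusted p = 0.329 with an estimated correlation). Of 13 goblet cell genes, 3 were higher and 0 lower (camera adjusted p = 0.0261, and adjusted p = 0.618 with an estimated correlation), among them Creb3l1 (0.94 ± 0.17). Of 13 tuft cell genes, 5 were higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.329 with an estimated correlation). Among the members higher were Alox5, Alox5ap and Ptgs1, which myeloid cells also express. Of 20 crypt stem cell genes, 0 were higher and 6 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 4.59e-06, and adjusted p = 0.25 with an estimated correlation). Of 18 Wnt target genes, 0 were higher and 7 lower, 2 and 10 adjusted over the list alone (camera adjusted p = 3.13e-05, and adjusted p = 0.25 with an estimated correlation). Axin2, a feedback target of Wnt signalling, was lower by -1.68 ± 0.17 (edgeR adjusted p = 0.00138) and Tnfrsf19 by -3.07 ± 0.38. Of 21 G2/M phase genes, 0 were higher and 2 lower, 0 and 21 adjusted over the list alone (camera adjusted p = 1.31e-08, and adjusted p = 0.367 with an estimated correlation). Of 22 S phase genes, 1 was lower, 9 adjusted over the list alone (camera adjusted p = 2.5e-06, and adjusted p = 0.438 with an estimated correlation). Of 18 interferon response genes, 0 were higher and 4 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 4e-05, and adjusted p = 0.329 with an estimated correlation). Of 24 fetal-like genes 2 were higher and 0 lower (camera adjusted p = 0.773), namely Gja1 (7.20 ± 0.98) and Spp1 (2.76 ± 0.59), whose cell source was not tested. Of 16 Paneth cell genes 0 passed (camera adjusted p = 0.356). The calls of Alox5, Alox5ap, Ptgs1 and Spp1 ended without COL_cWRNE replicate 1 or 3, those of Alox5, Ptgs1 and Spp1 also without COL_cWRNE replicate 2. Those of Alox5ap, Ptgs1 and Spp1 ended without VIL replicate 2. Over these settings the log2 fold changes were 2.08 to 3.94 (edgeR adjusted p of 0.0515 to 0.13). With all libraries Alox5, Alox5ap and Spp1 were at 3.52, 3.57 and 2.76. Without VIL replicate 3 Alox5 was at 2.59, without VIL replicate 2 Alox5ap was at 2.72 and Spp1 at 2.08, and without COL_cWRNE replicate 2 Alox5ap was at 4.34.

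More lists were called here. Of 5 endothelial genes, 0 passed over all genes, 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.329 with an estimated correlation), with a median log2 fold change of 2.28. Of 19 enteroendocrine genes, 0 were higher and 2 lower (camera adjusted p = 0.00113, and adjusted p = 0.466 with an estimated correlation), with a median of -0.80. Of 11 immediate early and heat shock genes, 0 were higher and 2 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 0.000858, and adjusted p = 0.25 with an estimated correlation). Of 15 unfolded protein and integrated stress response genes, 0 were higher and 2 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.438 with an estimated correlation). Of 16 cholesterol synthesis genes, 0 passed (camera adjusted p = 0.03, and adjusted p = 0.62 with an estimated correlation), with a median of -0.29.

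Genes with the largest increases in villus-derived cultures, all at 0 counts in COL_cWRNE, encode matrix metalloproteinases and proteins of myeloid cells and fibroblasts. Beside Col3a1, these were Mmp9 (at least 7410-fold), Mmp13 (at least 5790-fold), Mmp2 (at least 2200-fold), the C-type lectin gene Clec4n (at least 2060-fold), Lilrb4a (at least 1860-fold), the decorin gene Dcn (at least 1730-fold) and the integrin gene Itgb2 (at least 1670-fold). Without VIL replicate 3 the bounds were 2360-fold for Mmp9, 2300-fold for Mmp13, 1050-fold for Mmp2, 1320-fold for Clec4n, 1190-fold for Lilrb4a and 1100-fold for Itgb2, and without VIL replicate 2 they were 2500-fold for Col3a1 and 1060-fold for Dcn. The largest decreases were those of Mslnl (-3.22 ± 0.33), Tnfrsf19, Ly6c1 (-2.82 ± 0.49), Slc14a1 (-2.67 ± 0.61), the interferon-induced genes Isg15 (-2.67 ± 0.5) and Cmpk2 (-2.59 ± 0.36), Il18rap (-2.49 ± 0.31) and Slc28a3 (-2.40 ± 0.33). Alpi was at 2.92 ± 0.62 (edgeR adjusted p = 0.0227), Apoa4 at 4.02 ± 0.77 (edgeR adjusted p = 0.0156) and Muc2 at 2.90 ± 0.6 (edgeR adjusted p = 0.021). Lgr5 (-0.89 ± 0.39, edgeR adjusted p = 0.213), Olfm4 (-2.55 ± 1.06, 0.192), Mki67 (-0.82 ± 0.32, 0.167), Lyz1 (1.39 ± 0.69, 0.278) and Chga (0.30 ± 0.84, 0.878) did not pass. Neither did Ly6a (-0.69 ± 0.37, edgeR adjusted p = 0.315), Clu (0.17 ± 0.29, 0.779) and Anxa1 (-1.01 ± 0.3, 0.0724). The count of 1276 was 371, 474 and 351 without COL_cWRNE replicate 1, 2 and 3, and 2050 and 678 without VIL replicate 1 and 2, 743 with only the 6 compared libraries and 874 with a replicate block. The calls of Alpi, Apoa4, Muc2, Mmp9, Mmp2 and Dcn ended without any 1 of the COL_cWRNE replicates (edgeR adjusted p of 0.0531 to 0.104). Those of Slc14a1 and Isg15 ended without COL_cWRNE replicate 1 or 3 (edgeR adjusted p of 0.0551 to 0.115), and those of Mmp9, Mmp2, Dcn, Slc14a1 and Isg15 also without VIL replicate 2. Without VIL replicate 1, Alpi was at 1.82, Apoa4 at 2.69 and Muc2 at 2.05.

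Against crypt-derived cultures in Matrigel, origin, matrix and medium changed together, and 7789 of 16699 genes passed by edgeR, 4504 higher and 3285 lower in VIL. Which cells in VIL held the list transcripts was not tested. All 24 fetal-like genes were higher (camera adjusted p = 1.31e-14, and adjusted p = 0.356 with an estimated correlation), with Ly6a at 6.17 ± 0.46, Anxa1 at 5.50 ± 0.36, Clu at 5.23 ± 0.35 and Ereg at 4.64 ± 0.27. Of 21 YAP target genes, 20 were higher and 0 lower (camera adjusted p = 3.77e-09, and adjusted p = 0.356 with an estimated correlation), with Myof at 5.65 ± 0.45. Of 22 integrin, laminin and focal adhesion genes, 21 were higher, 22 adjusted over the list alone (camera adjusted p = 7.42e-08, and adjusted p = 0.404 with an estimated correlation). All 21 G2/M phase and all 22 S phase genes were lower (camera adjusted p = 4.65e-07 and 5.41e-08, and adjusted p = 0.467 and 0.464 with an estimated correlation), Mki67 by -1.49 ± 0.32. Of 19 enteroendocrine genes, 0 were higher and 13 lower, 16 adjusted over the list alone (camera adjusted p = 3.72e-06, and adjusted p = 0.419 with an estimated correlation), among them the somatostatin gene Sst (-7.54 ± 0.79) and Gcg (-5.90 ± 0.65). Of 24 absorptive enterocyte genes, 3 were higher and 10 lower, 3 and 12 adjusted over the list alone (camera adjusted p = 9.74e-05, and adjusted p = 0.464 with an estimated correlation), with Apoa4 at -4.32 ± 0.73 and Fabp2 at -2.94 ± 0.18. Olfm4 was at -7.67 ± 1.33, whereas Lgr5 (-0.49 ± 0.38, edgeR adjusted p = 0.314), Alpi (0.25 ± 0.58, 0.747), Lyz1 (-0.92 ± 0.69, 0.292), Muc2 (0.97 ± 0.56, 0.182) and Chga (-2.29 ± 0.86, 0.0527) did not pass. Without VIL replicate 1, Olfm4 was at -9.11, Apoa4 at -5.62 and Gcg at -6.83, without VIL replicate 2 Sst was at -9.67, and without VIL replicate 3 Myof was at 5.04.

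The largest increases against Matrigel were again of genes at 0 counts in MG_Control, namely Spp1, which encodes osteopontin (at least 23300-fold), Gpnmb (at least 17700-fold), Mmp12 (at least 8810-fold), Mmp9 (at least 7250-fold), Gabrp (at least 6090-fold), Mmp13 (at least 5660-fold), Mmp10 (at least 5040-fold) and Col1a1 (at least 3680-fold). Gabrp was at 574 CPM in VIL replicate 2 and at 38.9 and 7.97 CPM in replicates 1 and 3, and its bound was 689-fold without replicate 2. That of Spp1 was 14600-fold without VIL replicate 2, and without VIL replicate 3 those of Mmp9, Mmp13 and Mmp10 were 2310-fold, 2250-fold and 2850-fold. Exosc6 was at 0 counts in VIL, at least 784-fold lower, but also in COL_cWRNE, so a difference in how these 6 libraries were sequenced or quantified was not excluded. Such a difference would bear on the whole comparison with Matrigel. Beside Olfm4 and Sst, the other large decreases were those of Dpysl5 (at least 287-fold), at 0 counts in VIL, and of Pcdh8 (-8.18 ± 0.9), Reg3a (-7.20 ± 0.66), Sfrp5 (-6.65 ± 0.77) and Ugt2b5 (-6.62 ± 0.57). All 9 immune and all 9 mesenchymal genes were higher (camera adjusted p = 1.61e-06 and 5.22e-05, and adjusted p = 0.356 and 0.419 with an estimated correlation). Here too the filter partly set this direction. Without VIL replicate 1, Olfm4 was at -9.11, Reg3a at -7.79 and Ugt2b5 at -7.33. Without VIL replicate 2 Sst was at -9.67, and Pcdh8, whose counts in VIL came from that library alone, at -11.73, which depended on the prior count.

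Further lists were called here. Of 32 p53 target genes, 27 were higher and 1 lower (camera adjusted p = 2.02e-08, and adjusted p = 0.356 with an estimated correlation). Of 15 NF-kB and inflammatory genes, 14 were higher and 0 lower (camera adjusted p = 2.54e-05, and adjusted p = 0.196 with an estimated correlation). Of 11 immediate early and heat shock genes, 10 were higher and 0 lower (camera adjusted p = 1.56e-05, and adjusted p = 0.196 with an estimated correlation). Of 6 gastric and Brunner gland genes, 4 were higher and 0 lower (camera adjusted p = 0.0377, and adjusted p = 0.356 with an estimated correlation). Of 16 Paneth cell genes, 1 was higher and 4 lower (camera adjusted p = 0.0187, and adjusted p = 0.618 with an estimated correlation). Of 15 5-FU metabolism genes, 1 was higher and 8 lower (camera adjusted p = 0.00551, and adjusted p = 0.514 with an estimated correlation). Of 15 unfolded protein and integrated stress response genes, 2 were higher and 8 lower, 2 and 10 adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.569 with an estimated correlation). Of 16 cholesterol synthesis genes, 0 were higher and 8 lower (camera adjusted p = 0.0014, and adjusted p = 0.514 with an estimated correlation).

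The comparison of crypt-derived cultures in collagen with cWRNE medium against those in Matrigel isolated culture from tissue source, with matrix and medium changing together; 5556 of 16699 genes passed by edgeR, 3364 higher and 2192 lower. Of 24 fetal-like genes, 23 were higher and 0 lower (camera adjusted p = 7.86e-18, and adjusted p = 0.234 with an estimated correlation), with Ly6a at 6.86 ± 0.47, Anxa1 at 6.51 ± 0.38 and Clu at 5.05 ± 0.35. Of 21 YAP target genes, 19 were higher and 0 lower (camera adjusted p = 1.78e-10, and adjusted p = 0.234 with an estimated correlation). Of 18 interferon response genes, 16 were higher and 0 lower, 18 adjusted over the list alone (camera adjusted p = 3.51e-09, and adjusted p = 0.234 with an estimated correlation), with Bst2 at 2.46 ± 0.21 and Isg15 at 5.12 ± 0.57. Of 24 absorptive enterocyte genes, 0 were higher and 19 lower, 20 adjusted over the list alone (camera adjusted p = 1.39e-09, and adjusted p = 0.234 with an estimated correlation), with Apoa4 at -8.34 ± 0.9, Fabp2 at -5.13 ± 0.2 and Alpi at -2.68 ± 0.61. Of 19 enteroendocrine genes, 2 were higher and 10 lower, 2 and 14 adjusted over the list alone (camera adjusted p = 0.000144, and adjusted p = 0.53 with an estimated correlation). Of 9 mesenchymal genes 1 was higher and 1 lower, and of 9 immune genes 1 was higher (camera adjusted p = 0.993 and 0.76). Olfm4 was at -5.12 ± 1.18, and Lgr5 (0.40 ± 0.38, edgeR adjusted p = 0.455) and Mki67 (-0.67 ± 0.32, edgeR adjusted p = 0.134) did not pass.

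At 0 counts in MG_Control and higher in collagen with cWRNE medium were Stra6 (at least 9500-fold), Spp1 (at least 3460-fold), the Wnt ligand genes Wnt7b (at least 1770-fold), Wnt10a (at least 1710-fold) and Wnt7a (at least 1390-fold), Prss22 (at least 1050-fold), Cdh13 (at least 994-fold) and Ccdc80 (at least 982-fold). Exosc6 was at 0 counts in COL_cWRNE, at least 881-fold lower, with the same limit as for VIL. The other large decreases beside Apoa4 were those of Cfhr2 (at least 607-fold), at 0 counts in COL_cWRNE, Slc6a19 (-8.56 ± 1.32), Reg3a (-8.32 ± 0.7), Ugt2b5 (-7.68 ± 0.61), Ces1g (-7.29 ± 1.15) and Spink1 (-7.19 ± 1.18). Lyz1 (-2.32 ± 0.72, edgeR adjusted p = 0.033), Muc2 (-1.93 ± 0.58, 0.03) and Chga (-2.59 ± 0.88, 0.046) passed. Each call ended without any 1 of the 6 compared libraries, with log2 fold changes of -2.66 to -2.14, -1.99 to -1.77 and -2.73 to -2.38 and edgeR adjusted p up to 0.117, 0.105 and 0.141. The shared fit also took its spread from VIL, which was not compared here and varied more. Lyz1 was at 1820 ± 1910 CPM in VIL, 3380 ± 462 CPM in MG_Control and 700 ± 266 CPM in COL_cWRNE. Muc2 and Chga were at 127 ± 108 and 18.2 ± 19.1 CPM in VIL. The count of 5556 fell to 3630 without MG_Control replicate 2 and to 3654 without COL_cWRNE replicate 2. The counts of Slc6a19 in COL_cWRNE came from replicate 2 alone, and without it the value, -14.02, depended on the prior count. Without replicate 2, Reg3a was at -7.69 and Ces1g at -6.67, and without replicate 3, Ces1g was at -8.06 and Spink1 at -8.66.

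Further lists were called here. Of 22 integrin, laminin and focal adhesion genes, 20 were higher and 0 lower, 21 and 0 adjusted over the list alone (camera adjusted p = 6.48e-10, and adjusted p = 0.251 with an estimated correlation). Of 32 p53 target genes, 25 were higher and 1 lower, 28 and 2 adjusted over the list alone (camera adjusted p = 6.37e-09, and adjusted p = 0.234 with an estimated correlation). Of 15 NF-kB and inflammatory genes, 11 were higher and 1 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.116 with an estimated correlation). Of 11 immediate early and heat shock genes, 10 were higher and 0 lower (camera adjusted p = 6.51e-09, and adjusted p = 0.112 with an estimated correlation). Of 18 Wnt target genes, 10 were higher and 0 lower, 11 and 0 adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.234 with an estimated correlation). Of 6 gastric and Brunner gland genes, 4 were higher and 0 lower (camera adjusted p = 0.0296, and adjusted p = 0.234 with an estimated correlation). Of 13 goblet cell genes, 0 were higher and 4 lower, 0 and 5 adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.586 with an estimated correlation). Of 16 Paneth cell genes, 1 was higher and 3 lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.747 with an estimated correlation). Of 15 5-FU metabolism genes, 1 was higher and 6 lower, 1 and 7 adjusted over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.675 with an estimated correlation). Of 16 cholesterol synthesis genes, 0 were higher and 2 lower (camera adjusted p = 0.039, and adjusted p = 0.71 with an estimated correlation). Of 21 G2/M phase genes, 0 passed (camera adjusted p = 0.0327, and adjusted p = 0.748 with an estimated correlation), with a median of -0.41.

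**Figure D3:**
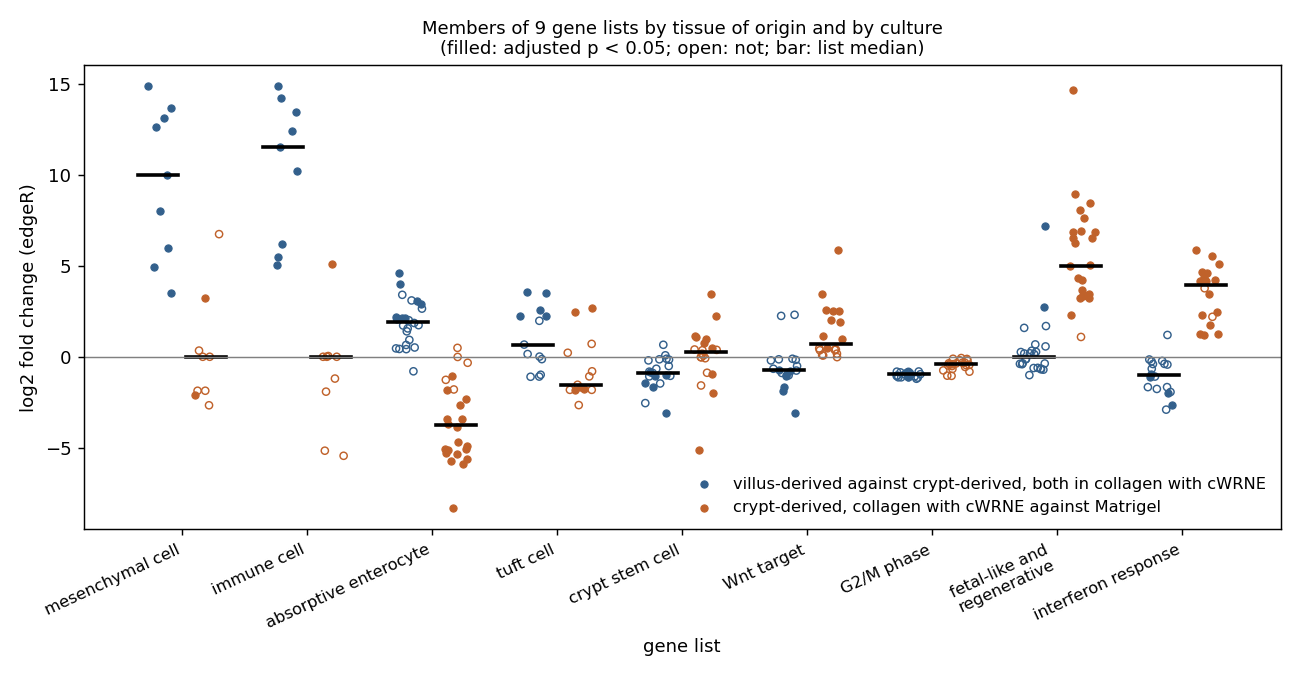
Log2 fold changes (edgeR, vertical axis) of the members of 9 gene lists for villus-derived against crypt-derived cultures in collagen with cWRNE medium, and for crypt-derived cultures in that culture against Matrigel. Filled points had an adjusted p under 0.05, open points did not, and bars are list medians. Values of genes at 0 counts in one group are fitted, depend on the prior count and are no bound. The immune and mesenchymal genes, 9 of each, were higher in villus-derived cultures, and the absorptive enterocyte median was 1.93 for villus against crypt and -3.77 for cWRNE medium and collagen against Matrigel.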

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

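The 10 tests of explanations below, and the splits for cWRNE against ENRW medium, were chosen only after the result they concern was seen, whereas the counts over splits for the other 7 comparisons were planned.

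The response to 5-FU differed between the 2 culture systems by the interaction test, for 1360 genes and for the lists and genes below; values are collagen minus Matrigel. List medians were -0.68 for p53 target, -1.11 for fetal-like, -1.15 for YAP target, -1.87 for Paneth, -1.12 for goblet, -1.04 for enteroendocrine, -1.17 for tuft and -2.49 for absorptive enterocyte genes. They were 0.28 for G2/M, 0.65 for S phase, -1.79 for interferon, 0.27 for integrin, 0.34 for cholesterol synthesis, -0.56 for immediate early, -1 for proximal and -2.95 for distal small intestine genes. With an estimated correlation, 0 of these list calls held by camera (lowest adjusted p = 0.0698). For the whole interaction, 2 of 100 splits of the libraries, the real one among them, gave as many genes by edgeR. This does not exclude chance: the 85 splits that mixed treated and untreated libraries in both matrices, which leaves the effect of 5-FU in the residual, called at most 0 genes, and the splits ignored the pairing by replicate number. The highest other count, 7388, came from exchanging the treatment labels in collagen alone, which adds the 2 effects of 5-FU and points to this structure of the samples; the next highest was 1160.

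Single genes with a positive interaction were Gkn3 (2.97 ± 0.39), Arhgef4 (2.80 ± 0.74), Ntn4 (2.60 ± 0.48), Rassf5 (2.57 ± 0.6), Prss12 (2.56 ± 0.36), Clca3b (2.31 ± 0.23), Pm20d1 (2.21 ± 0.37), Nr4a2 (1.85 ± 0.42) and Tyms (0.75 ± 0.16). A positive value need not be a stronger response in collagen. Gkn3 went from 22.3 to 3.38 CPM with 5-FU in Matrigel and from 4.85 to 6.12 CPM in collagen. Clca3b went from 1330 to 290 CPM in Matrigel and from 659 to 754 CPM in collagen. Negative were Clec2h (-8.70 ± 0.67), Cdkn1a (-1.03 ± 0.26), Olfm4 (-1.55 ± 0.41), Lyz1 (-1.75 ± 0.21) and Ly6a (-2.28 ± 0.48). Olfm4 fell more in collagen, with log2 fold changes of -2.71 in Matrigel and -4.26 in collagen. Ly6a rose in both, from 17 to 196 CPM in Matrigel and from 544 to 1380 CPM in collagen. Fitted values of genes at 0 counts in a group depend on the prior count and are no bound: Pakap -9.91, Ggta1 -7.85, Dscaml1 -6.68, Mslnl -6.63, Axl -6.42 and Hmgcll1 -5.97, at 0 in MG_Control, and Slc5a4b -6.30, at 0 in COL_5FU. The direction of 5 of them depended on the measure: by limma-trend on log2(TPM + 1), Ggta1 was at 0.50, Dscaml1 at 0.79, Mslnl at 0.74, Axl at 0.77 and Hmgcll1 at 1.68. Axl, for example, was at 0 and 6.06 CPM in Matrigel and at 0.694 and 12.1 CPM in collagen, so it was higher with 5-FU in both. Of the 1047 genes with a lower response, 33 had at most 3 counts over MG_Control and 23 over COL_5FU.

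Several of these calls ended when 1 library was left out. Without MG_Control replicate 1, MG_5FU replicate 2 or 3, or COL_5FU replicate 1 or 2, Arhgef4 was at 2.43 to 2.85 (edgeR adjusted p of 0.0562 to 0.0786), and without COL_5FU replicate 2 Rassf5 was at 2.39 (edgeR adjusted p = 0.0506); without COL_Control replicate 1 it was at 3.26 and Ggta1 at -7.25, and without COL_Control replicate 2 Axl was at -5.74, whereas without COL_5FU replicate 1 Clec2h, then at 0 counts in COL_5FU, was at -10.52, which depended on the prior count. Slc5a4b was at -6.52 to -6.03 without any 1 of the COL_Control or COL_5FU replicates (edgeR adjusted p of 0.0545 to 0.102). Cdkn1a was at -1.04 to -0.91 without MG_Control replicate 2, MG_5FU replicate 1 or 3, COL_Control replicate 1 or 3, or any 1 COL_5FU replicate (edgeR adjusted p of 0.0536 to 0.0715). Olfm4 was at -1.58 to -1.26 without MG_Control replicate 1 or 2, MG_5FU replicate 2 or 3, COL_Control replicate 1 or 3, or COL_5FU replicate 1 or 2 (edgeR adjusted p of 0.0507 to 0.0917). In a fit of all 18 libraries the calls of Arhgef4, Rassf5, Prss12, Dscaml1, Axl, Slc5a4b, Cdkn1a, Tyms, Olfm4 and Lyz1 ended.

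The 85 genes of the 5 lineage lists (Paneth, goblet, enteroendocrine, tuft and absorptive cells) had a median log2 fold change with 5-FU of 1.48 in Matrigel and -0.28 in collagen, and 50 were lower and 0 higher by the interaction. Against a difference in scaling, their median interaction lay -1.74 from that of all genes, where the lowest of 10000 random lists reached -0.22. The 5 lists rose unequally in Matrigel (permutation p = 0.00022 over 100000 permutations, treating correlated genes as independent). Loss of proliferating cells alone stays open, since list genes need not be silent in them. Against a detection floor in collagen, the 37 genes with a mean of at least 10 CPM in both COL_Control and COL_5FU had a median interaction of -1.81 (bounds -2.12 to -1.41). A floor stays open for the other 48 genes, under 10 CPM in a collagen group, and whether matrix or medium may underlie the difference stays open and untested, since the 2 changed together.

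COL_Control replicate 3, with a female level of Xist (177 CPM against 172 to 262 in the other female libraries), held 738 counts of 4 Y-linked genes, 18.7% of the male mean. Against material of a male library of another group, genes such a share would raise stood at no more than 0.079 of the level needed (the highest of 5 medians). Against misassigned reads across the run, the highest count in the other 11 female libraries was 1. Material of COL_Control replicate 2, the male library of its own group, may be present, and stays open: Xist at 82.6% of the mean of the other female libraries does not decide it. No biological explanation was tested; without this library 4817 genes passed with 5-FU in collagen, 951 by the interaction and 4485 for collagen against Matrigel.

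Macrophage and fibroblast transcripts were found in all 3 VIL libraries, where the 18 immune and mesenchymal genes summed to at least 1053.3 CPM. Against reads of another library of the series, the highest sum in the other 15 libraries was 32 CPM. Macrophages and fibroblasts carried over from the villus tissue may be the source, and both stay open: across genes, the log2 ratios between VIL libraries had SDs of up to 0.89 and 0.9, too wide to show 1 shared proportion. Lyz2 stood at 832.83, 2306.18 and 3403.07 CPM and C1qa at 27.04, 89.45 and 138.85 CPM in VIL replicates 1, 2 and 3, and 4 of the 9 genes of each list reached 1 CPM in another library. Of the 949 genes higher than in COL_cWRNE, 285 were under 1 CPM in each of the other 15 libraries, and expression of such genes by the epithelium was not tested.

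For the other comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The highest other count by edgeR was 0, against real counts of 1276 to 7789. This does not bear on chance, since each other split mixed the groups and left their difference in the residual.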

How the results depend on the processing

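Counts of passing genes changed with the fold size required, the tool and the libraries included; the cause was not tested, except where fewer genes or libraries entered. The self-test recovered 1.5-fold changes in 15.4% (5-FU in Matrigel), 18.8% (5-FU in collagen), 3.1% (interaction) and 0% (villus against crypt in collagen). Fewer genes changed there than passed here, so real shares may differ. The pseudocount alternative was not run, since counts were deposited.

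With an absolute log2 fold change of at least 1, 2167, 2218, 802, 2215, 4794, 3358 and 1543 genes passed for 5-FU in Matrigel, 5-FU in collagen, the interaction, collagen against Matrigel, villus against Matrigel, cWRNE against Matrigel and cWRNE against ENRW. For the interaction, DESeq2 gave 2219 and the fit of all 18 libraries 521. For villus against crypt in collagen, DESeq2 gave 2264, the fit of all libraries 2480, genes of at least 10 CPM 847, and only the compared groups 743. VIL replicate 1 as the only villus-derived library gave 4637 for villus against Matrigel; this lone library, which still held macrophage and fibroblast transcripts, is assumed to vary like the other groups, so the count is not comparable with those of replicated groups. Of 109 list calls by camera, 1 held with an estimated correlation and 111 were made by fry, 87 of them shared. By limma-trend on log2(TPM + 1), interactions changed sign for Ggta1 (0.50), Dscaml1 (0.79), Mslnl (0.74), Axl (0.77) and Hmgcll1 (1.68), all at 0 in MG_Control. With that lone library and the same assumption, Agr2 (0.71) and Ret (-0.15) had the opposite sign against Matrigel.

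Leaving out 1 library gave 4139 to 4610 genes for 5-FU in Matrigel, 4566 to 5584 in collagen, 931 to 1297 for the interaction, 3977 to 4755 for collagen against Matrigel and 5752 to 8604 for villus against Matrigel. For villus against crypt it gave 351 (without COL_cWRNE replicate 3) to 2050 (without VIL replicate 1), with 371, 474 and 678 without COL_cWRNE replicate 1 and 2 and VIL replicate 2. For cWRNE against Matrigel it gave 3630 to 4324, with 3654 without COL_cWRNE replicate 2 and 3630 without MG_Control replicate 2. For cWRNE against ENRW it gave 1907 to 2669: 1907 and 2113 without COL_Control replicate 3 and 2, and 2110 and 1908 without COL_cWRNE replicate 1 and 2.

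Library totals in place of TMM moved the median of all genes from 0.063 to -0.087 for 5-FU in Matrigel, from -0.025 to -0.130 in collagen and from 0.003 to -0.157 for cWRNE against ENRW; TPM moved it to -0.224, -0.126, 0.126 (interaction) and 0.225 (collagen against Matrigel). On TPM the list medians of integrin genes with 5-FU in Matrigel (-0.06) and of unfolded protein response genes for collagen against Matrigel (0.08) changed sign.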

Other observations

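A comparison chosen after the data were seen set cWRNE against ENRW medium for crypt-derived cultures in collagen. It passed 3184 of 17708 genes by edgeR, 2325 higher and 859 lower. Of 19 interferon response genes, 14 were higher and 0 lower (camera adjusted p = 1.43e-11, and adjusted p = 0.182 with an estimated correlation), among them Irf7 (2.35 ± 0.32). Of 24 fetal-like genes, 22 were higher and 0 lower (camera adjusted p = 2.52e-15, and adjusted p = 0.213 with an estimated correlation), with Anxa8 at 5.32 ± 0.42, and 17 of 21 YAP target genes were higher (camera adjusted p = 1.73e-09, and adjusted p = 0.237 with an estimated correlation). Integrin, laminin and focal adhesion genes were 19 higher and 0 lower (camera adjusted p = 7.17e-12, and adjusted p = 0.213 with an estimated correlation), with Itgb6 at 2.29 ± 0.24 and Lama3 at 6.43 ± 0.74. Of 7 gastric and Brunner gland genes, 6 were higher (camera adjusted p = 3.68e-05, and adjusted p = 0.182 with an estimated correlation), among them Gkn3 (3.09 ± 0.28) and Ctse (5.69 ± 0.73). Sst changed by -4.61 ± 0.51. Exosc6 was at least 423-fold lower, so a difference in sequencing or quantification may bear on this whole comparison. Lama3 was at 7.49 without COL_Control replicate 2. Of 32 p53 target genes, 15 were higher and 0 lower, 20 and 1 adjusted over the list alone (camera adjusted p = 1.05e-05, and adjusted p = 0.364 with an estimated correlation). Of 18 Wnt target genes, 9 were higher and 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 6e-04, and adjusted p = 0.237 with an estimated correlation). Of 22 S phase genes, 0 were higher and 7 lower, 0 and 11 adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.614 with an estimated correlation). Of 21 G2/M phase genes, 0 were higher and 1 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.000361, and adjusted p = 0.651 with an estimated correlation). Of 19 enteroendocrine genes, 2 were higher and 8 lower (camera adjusted p = 0.00487, and adjusted p = 0.651 with an estimated correlation). Of 24 absorptive enterocyte genes, 1 was higher and 5 lower (camera adjusted p = 0.0361, and adjusted p = 0.651 with an estimated correlation). Of 16 cholesterol synthesis genes, 0 were higher and 3 lower, 0 and 5 adjusted over the list alone (camera adjusted p = 6e-04, and adjusted p = 0.614 with an estimated correlation). Of 15 NF-kB and inflammatory genes, 3 were higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.614 with an estimated correlation). Of 15 unfolded protein and integrated stress response genes, 5 were higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0417, and adjusted p = 0.651 with an estimated correlation). The count of 3184 was 2113 and 1907 without COL_Control replicate 2 and 3, and 2110 and 1908 without COL_cWRNE replicate 1 and 2.

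Exosc6 (ENSMUSG00000109941.2), which encodes a subunit of the RNA exosome, had 0 counts in all 6 COL_cWRNE and VIL libraries and 7 to 54.6 CPM in the other 12. It was singled out after its values were seen. It was the only gene, 1 in all, with at most 2 counts in these libraries and over 1 CPM in each other. Another way of sequencing or quantifying these 6 libraries, such as another annotation, was not excluded, so a difference in expression is not shown.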
